A study of Homo sapiens with 2 samples.

How the data were processed

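A549 cells were grown in 60-mm dishes in DMEM with 0.45% glucose and 10% fetal calf serum, and bradykinin was given at 100 nM for 30 min in medium with 0.1% serum, per the labels' protocols. The control received DMSO for 30 min. Whether its medium was also changed to 0.1% serum is not given in the sources used here. Total RNA from each was amplified to Cy3-labelled cRNA with an Agilent low-input kit, per the labels' protocols, and hybridised to 1 array per group. That kit's usual priming starts at poly(A) tails, but the primer used is not given in the sources used here.

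The scanner files hold spot intensity values on a linear scale, per the file headers. Agilent Feature Extraction made them, as version 10.7.1.1 per the file headers and version 9.5.1.1 per the submitters' processing notes; the sources used here do not settle which applies. The column used in the main analysis was the processed signal, which is background-subtracted intensity as deposited. The authors' series matrix was also read. Its scale is linear intensity and its columns ranked probes like the scanner values (Spearman 1.00 for each array). Both columns had a median of 16.3 and differed by at most 0.446 at any rank, as quantile normalization leaves them, so they are centred on a shared distribution; the authors' exact step is not given in the sources used here.

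Control spots and spots flagged as outliers (221 on the DMSO array, 171 on the bradykinin array) were left out. The log2 of the processed signal was taken, the array's 75th percentile over non-control spots was subtracted, and spots of a probe were averaged. A gene's value was the mean of its probes that were well above background on both arrays. Of 50598 probes, 22357 met this, for 16976 genes or transcripts; 12936 of these had 1 measured probe. Gene names came from the files and were updated through the accession, or a unique older symbol, in a RefSeq gene table of assembly GRCh38.p14, used for names only; 31412 probes (62.1%) had a name in it. Probe coordinates are those of the files, on hg19. No annotation of that build was used here, so exons and UTRs are not stated for the probes. Genes on the Y chromosome and XIST and its antisense gene were counted but are neither listed nor plotted.

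Local background had a median of 63.0 on the DMSO array and 89.0 on the bradykinin array. Repeated spots of 623 probes had a median SD of 0.06 log2 units on the DMSO array and 0.05 on the bradykinin array. Probes of the same gene (9421 probes of 4040 genes) had an SD of 0.39 in their log2 difference. The SD of the difference over all measured genes was 0.40, and across genes, which are not independent replicates, the arrays correlated with Spearman's rho 0.988. The number of arrays limits the precision: with 1 per group there was no test and no p-value, and differences were described by size.

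The groups, the lists and the rules were fixed before the data were examined. Named genes were, in each direction, the 12 with the largest difference among genes with a symbol, a mean signal at or above the median, no saturated probe and all measured probes on the same side of 0; the 3 with the largest at-least bound in each direction; both bradykinin receptors; and in each list up to 4 members with the largest absolute difference where it was at least 0.5 log2 units. A gene that this rule names is not reported here. Of 25 lists 24 had at least 5 measured members, and for each of these the median difference was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. A list under the 2nd or over the 98th percentile was said to stand apart, which describes these 2 arrays and not the conditions. On simulated data with 16976 genes, an SD of 0.4 and 200 genes given a 4-fold difference, the 2-fold limit found 99.0% of the higher and 100% of the lower genes, and 1.19% of unaltered genes passed it. Of 200 simulated unaltered lists of 20 genes 4.0% lay outside the limits, and of 100 lists shifted by 0.5, 99.0% lay over the 98th percentile. The simulated noise was normal and independent between genes, so these shares follow largely from the settings. They check the calculation and do not give error rates for these 2 arrays.

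Alternatives were normexp background correction (offset 50) on mean signal and local background, quantile normalization, median scaling, subtraction of an intensity trend (lowess) or a slide position trend (loess), other background filters, the brightest probe of each gene, the series matrix, a 1.5-fold limit, and for lists unmatched random lists, the mean, and the list without its largest member. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.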

Results

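Transcript levels were measured in A549, a human lung adenocarcinoma line with properties of alveolar epithelial cells, on 1-colour Agilent arrays of 60-base probes. There were 2 groups with 1 array each: cells given DMSO for 30 min, and cells given 100 nM bradykinin for 30 min. Bradykinin is a vasoactive peptide cut from kininogen that acts mainly on the Gq-coupled B2 receptor, and less on the related B1 receptor. Of 58717 non-control spots, 28379 (48.3%) were well above background on the DMSO array and 31249 (53.2%) on the bradykinin array. The 75th percentile of processed signal was 312 on the DMSO array and 679 on the bradykinin array, and 0 spots were saturated on either. Differences below are log2 values of bradykinin over DMSO after each array was divided by its own 75th percentile, for 16976 genes or transcripts measured on both arrays.

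The comparison asked which transcripts differed between cells after 30 min of bradykinin and cells given DMSO. Among the lists, the highest median difference (0.70) was in immediate early genes, which cells transcribe within minutes of a stimulus. FOS, a subunit of the AP-1 transcription factor, was 69.1-fold higher on the bradykinin array (log2 difference 6.11, or 5.12 with normexp background correction). EGR1 and FOSB, which encode a zinc finger transcription factor and another AP-1 subunit, were not well above background on the DMSO array and were at least 388-fold and at least 100-fold higher on the bradykinin array. Replication-dependent histone genes and 18S ribosomal RNA lay in the opposite direction relative to the bulk of transcripts. All 17 measured members of the histone list were lower on the bradykinin array, and the 18S transcript (RNA18SN5) was 29.7-fold lower. By contrast, 28S ribosomal RNA (RNA28SN5), made from the same precursor, lay at -0.33.

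There is no replicate check on any difference, because each group had 1 array, and no p-value was computed. Each array was on a slide of its own, so slide and treatment cannot be told apart. The only spread that could be measured was technical: the SD of the log2 difference between probes of the same gene was 0.39 over 4040 genes.

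At least 2-fold higher on the bradykinin array were 78 of the 16976 genes or transcripts, and 402 were at least 2-fold lower. Those with a gene symbol numbered 45 and 277. The balance depended on the background filter and on scaling. The share of calls that were higher was 16.2% with the 75th percentile. It was 52.1% once probes well above background on at least 1 array were let in (592 higher and 544 lower). Many of the added higher calls used DMSO values that were not well above background. Of 2003 genes or transcripts well above background on the bradykinin array only, at-least bounds reached 2-fold for 45. Scaled to the spike-in controls, 99.9% of calls were higher, because the spike-in sequences lay 1.39 log2 units lower on the bradykinin array after percentile scaling. Every value below is therefore relative to the bulk of the transcripts, whose median difference was 0.05 with percentile scaling and 1.43 with spike-in scaling. At least 4-fold higher were 9 transcripts, of which 4 had a gene symbol, namely FOS, C20orf204, JUNB and IL6; these were listed after their values were seen. At least 4-fold lower were 29.

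**Figure D1:**
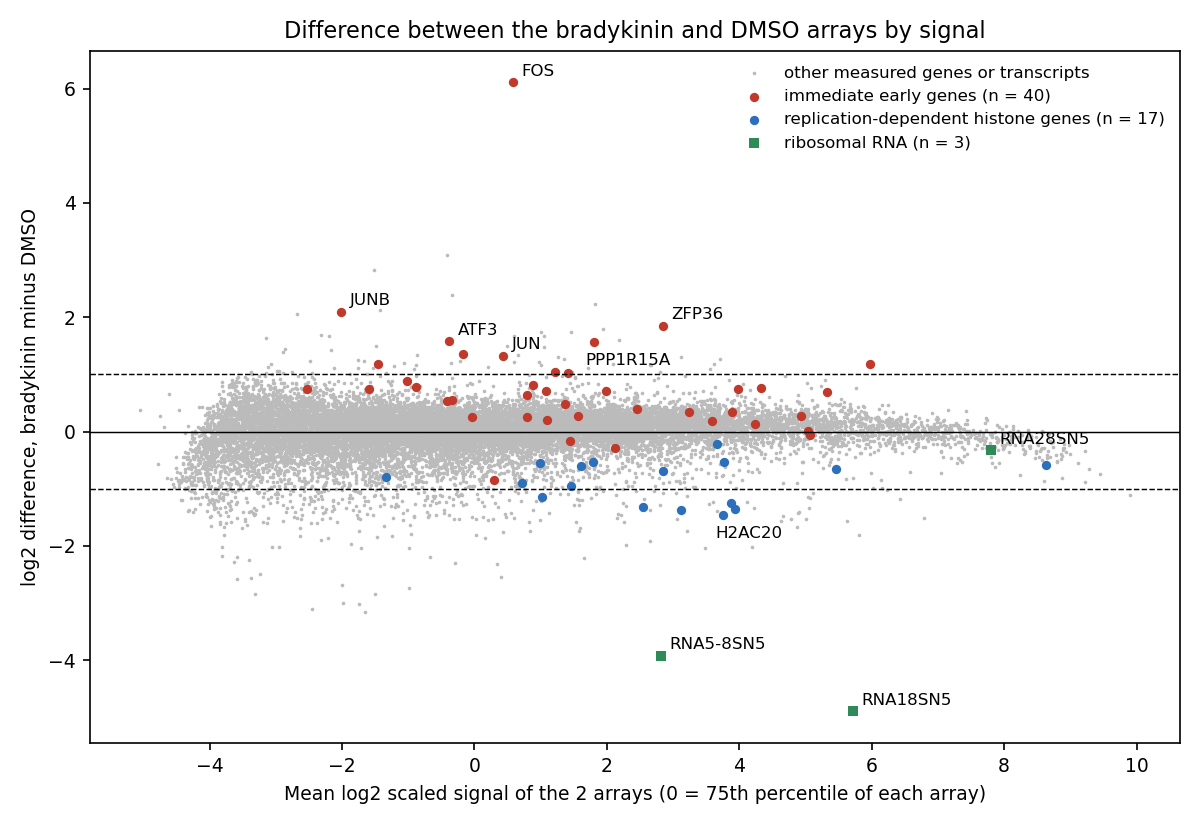
Log2 difference (bradykinin minus DMSO, vertical axis) against mean log2 scaled signal of both arrays (horizontal axis, 0 at each array's 75th percentile), 1 point per gene or transcript measured on both arrays. Dashed lines mark 2-fold; FOS stands alone at 6.11, and RNA18SN5 and RNA5-8SN5 at -4.89 and -3.92.

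The list of immediate early genes had 40 measured members out of 47, and 36 of them were higher on the bradykinin array, 11 by at least 2-fold. The list's median difference was 0.70, above all 10000 random lists of the same size and mean expression (100th percentile). The probe for FOS (chromosome 14, 75748214 to 75748273, hg19) had a processed signal of 56.1 on the DMSO array and 8443 on the bradykinin array. JUNB, another AP-1 subunit, was 4.28-fold higher (log2 difference 2.10, or 1.11 with normexp). ZFP36, which encodes the mRNA-destabilising protein tristetraprolin, was 3.62-fold higher. ATF3, a stress-inducible transcription factor, was 3.01-fold higher as the mean of 4 probes, which ranged from 0.37 to 2.16 log2 units. PPP1R15A, the regulatory subunit of an eIF2alpha phosphatase, was 2.95-fold higher, and JUN was 2.51-fold higher. The EGR1 probe (chromosome 5, 137804891 to 137804950, hg19) reached a signal of 14744 on the bradykinin array against 17.5 on the DMSO array. The FOSB probe (chromosome 19, 45978205 to 45978264, hg19) reached 3481 against 8.15. Another 2 members, EGR2 and NR4A1, were also well above background only on the bradykinin array, by at least 4.11-fold and at least 1.11-fold. The 4 members that were lower, named after their values were seen, were FOSL2 (-0.85), NFIL3 (-0.28), PHLDA1 (-0.17) and IER5 (-0.06).

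Feedback inhibitors of MAP kinase signalling were also higher as a list: 12 of 15 measured members lay above 0, with a median of 0.38 (100th percentile of random lists). DUSP5, a nuclear phosphatase of ERK, was 3.33-fold higher. DUSP1, a phosphatase of p38, JNK and ERK, was 1.97-fold higher. TRIB1, a pseudokinase shared with the immediate early list, was 1.68-fold higher, and SPRY4, an inhibitor of receptor tyrosine kinase signalling, was 1.66-fold higher, but SPRY4 lay at -0.029 with normexp and at 0.05 with no background filter. Without TRIB1 the list stayed at the 99.9th percentile.

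In the list of inflammatory and NF-kB target genes, 23 of 26 measured members lay above 0 and the median was 0.37 (100th percentile). IL6, the cytokine interleukin 6, was 4.18-fold higher, from a processed signal of 23.7 to 216. CXCL8, the neutrophil chemokine interleukin 8, was 2.72-fold higher, from 26.1 to 154. Both were dim on the DMSO array, and with normexp background correction their log2 differences were 0.86 and 0.38 in place of 2.06 and 1.44. With no background filter they were 0.62 and 0.30. CXCL2, another neutrophil chemokine, was 1.88-fold higher over 2 probes, and IL11, an IL-6 family cytokine, was 1.76-fold higher. The 3 members below 0, named after their values were seen, were TNFAIP3 (-0.60), TNFAIP2 (-0.13) and CXCL5 (-0.01). ZC3H12A, an endoribonuclease that degrades cytokine mRNAs and was in none of the lists, was 3.19-fold higher.

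**Figure D2:**
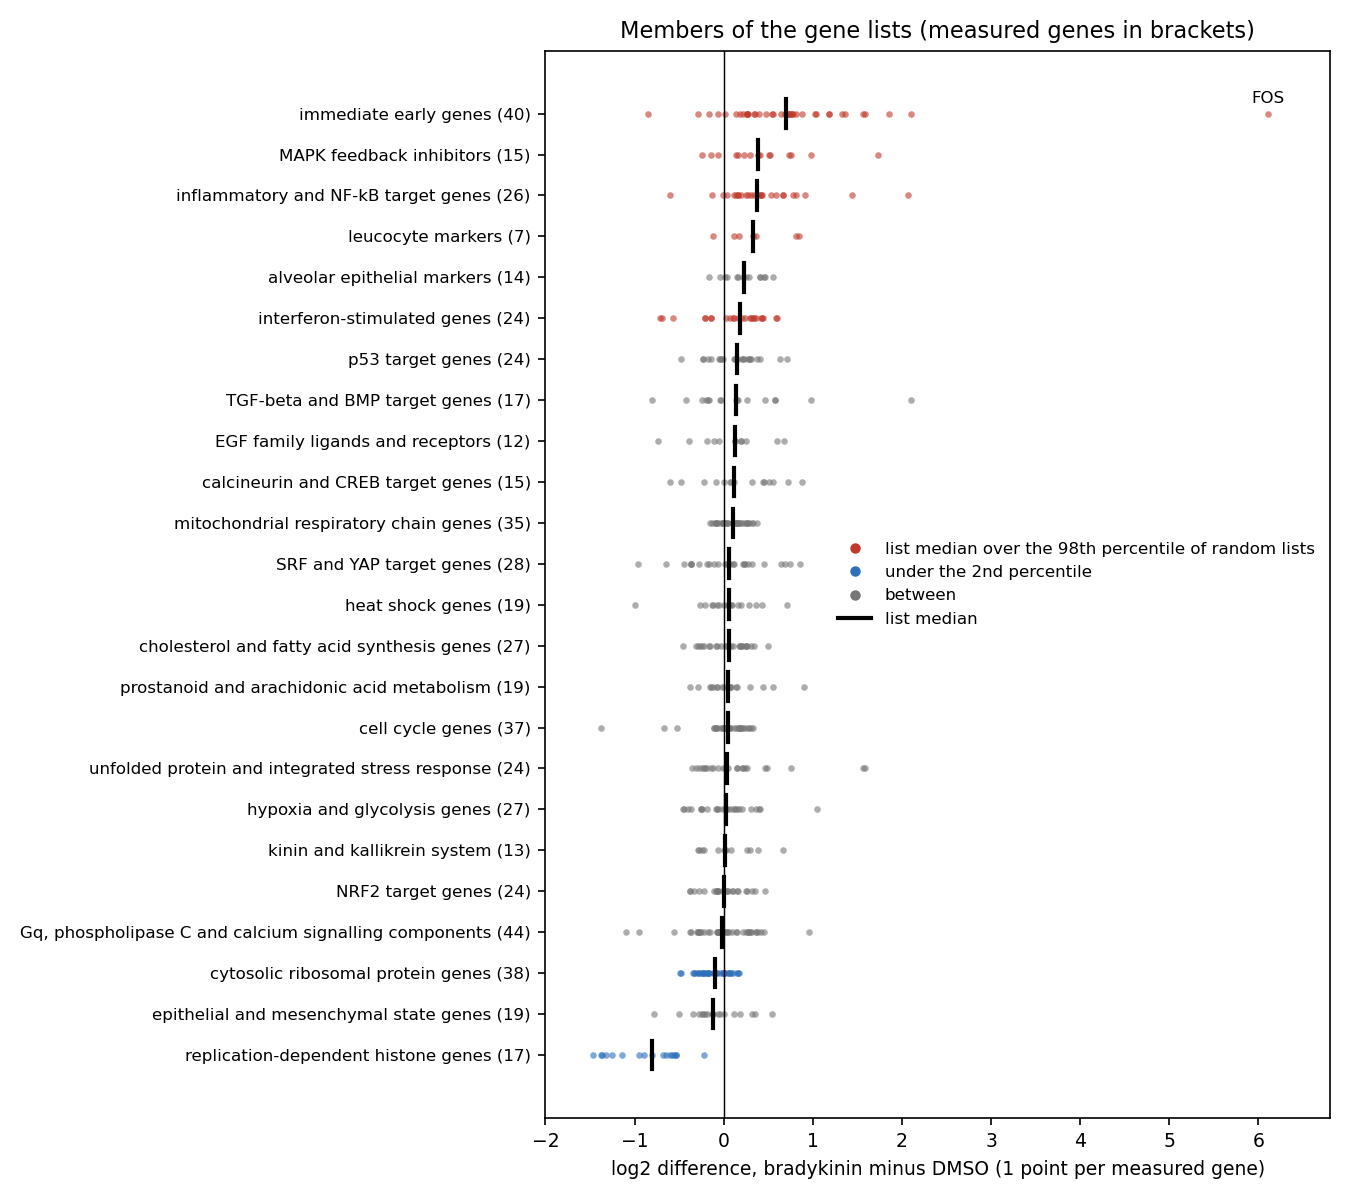
Log2 difference (bradykinin minus DMSO) of each measured member of the 24 lists with at least 5 measured genes, 1 point per gene, with the list median as a black bar and the number of measured genes in brackets. Red and blue lists had medians over the 98th or under the 2nd percentile of random lists. With percentile scaling the median was highest for immediate early genes (0.70) and lowest for replication-dependent histone genes (-0.80).

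Both bradykinin receptor genes were well above background on both arrays and differed little. BDKRB2, the constitutive B2 receptor, was 1.23-fold higher and BDKRB1, the inducible B1 receptor, 1.20-fold higher, less than the SD between probes of the same gene. The kinin and kallikrein list had a median of 0.01 over 13 measured members, with 8 above 0 and 5 below, and its largest difference was in the dipeptidyl peptidase gene DPP4 (1.59-fold higher, but -0.11 with normexp). Components of Gq, phospholipase C and calcium signalling had a median of -0.02, with 20 members above 0 and 24 below. Among them RGS16, which shortens G protein signalling, was 1.94-fold higher, but lay at 0.04 with normexp. The calcineurin subunit gene PPP3R1 was 2.14-fold lower, the plasma membrane calcium pump gene ATP2B1 was 1.94-fold lower, and the kinase gene CAMK2D was 1.48-fold lower.

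Target genes of calcineurin and CREB had a median of 0.11. Among them the orphan nuclear receptor genes NR4A2 and NR4A3 were 1.84-fold and 1.65-fold higher and the clock gene PER2 was 1.52-fold lower. NR4A3 lay at -0.10 with no background filter. The PER2 probe nearer the 5′ end gave -0.90 and the other -0.31. In prostanoid and arachidonic acid metabolism the median was 0.05. PTGS2, the inducible cyclooxygenase, was 1.46-fold higher and ALOX5AP, which presents arachidonic acid to 5-lipoxygenase, 1.87-fold higher, but ALOX5AP lay at -0.0048 with normexp and 0.13 with no background filter. EGF family ligands and receptors had a median of 0.12: the ligand genes AREG and HBEGF were 1.60-fold and 1.51-fold higher and BTC was 1.66-fold lower. HBEGF lay at -0.019 with normexp. SRF and YAP target genes had a median of 0.06, and here TAGLN, SRF and CCN1 were 1.81-fold, 1.67-fold and 1.61-fold higher while ANKRD1 was 1.95-fold lower. With normexp TAGLN lay at 0.27 and SRF at 0.06. The TGF-beta and BMP target list had a median of 0.13, with ATOH8 at 0.58 (-0.096 with normexp) and SKI, a repressor of TGF-beta signalling, 1.74-fold lower. None of these 5 lists stood apart from random lists in the main setting. That setting left out 3 calcineurin and CREB members well above background only on the bradykinin array. With probes well above background on at least 1 array, that list had a median of 0.44 (100th percentile), and with no background filter it was at the 99.4th percentile. Those settings use DMSO values near background. With at-least bounds for the members left out, the median was 0.23. The list shares NR4A1, NR4A2, NR4A3, EGR2, EGR3 and FOSB with the immediate early list, so its rise is not separate from that list's. The TGF-beta and BMP list was at the 99.3rd percentile by the mean. It shares JUNB (2.10) with the immediate early list, and 1 large member can move a mean. The mean without JUNB was not tested.

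The remaining stress, metabolic and cell state lists mostly lay near 0. Heat shock genes had a median of 0.05 with 12 members above 0 and 7 below. HSPA1L was 1.64-fold higher and HSP90AA1 1.99-fold lower, the latter over 3 probes from -1.49 to -0.25, of which the brightest gave -0.25. HSPA1L lay at -0.050 with normexp. The unfolded protein and integrated stress response list had a median of 0.03, although DDIT3, which encodes the transcription factor CHOP, was 1.69-fold higher beside ATF3 and PPP1R15A. Medians were 0.02 for hypoxia and glycolysis genes, in which BHLHE40 was 2.07-fold higher, and 0.00 for NRF2 target genes. The p53 target list had a median of 0.15, with PLK3 1.64-fold and FAS 1.55-fold higher. Cholesterol and fatty acid synthesis genes had a median of 0.05, and HMGCS1 was 1.42-fold higher. Mitochondrial respiratory chain genes had a median of 0.11. Alveolar epithelial markers had a median of 0.23, with AGER 1.47-fold higher. AGER lay at -0.0077 with normexp, -0.36 with probes well above background on at least 1 array and -0.54 with no background filter. Epithelial and mesenchymal state genes had a median of -0.12, with SNAI1 1.46-fold higher and ZEB1 and VIM 1.72-fold and 1.41-fold lower; the 2 ZEB1 probes gave -1.51 and -0.06. Cell cycle genes had a median of 0.05. In that list MKI67, CENPF and UBE2C were 2.59-fold, 1.59-fold and 1.44-fold lower, and the 3 MKI67 probes gave -1.93, -1.91 and -0.29. The CENPF probe nearer the 5′ end gave -0.96 and the other -0.38.

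Another 3 lists stood apart from random lists. Interferon-stimulated genes had a median of 0.19 (98.4th percentile), with IRF7 and OASL 1.51-fold higher and MX2 and DTX3L 1.64-fold and 1.61-fold lower. With normexp background correction that list had a median of -0.0048, was at the 86.3rd percentile, and OASL lay at -0.28. MX2 lay at 0.48 once probes well above background on only 1 array were let in. Leucocyte markers had a median of 0.33 over 7 measured members (99.4th percentile), with TYROBP 1.80-fold and ITGAM 1.76-fold higher. That list's call was lost under 4 alternatives: its median was -0.46 (33.1st percentile) with no background filter, and it was at the 97.5th percentile with normexp, where ITGAM lay at -0.27 and TYROBP at 0.36. Cytosolic ribosomal protein genes had a median of -0.10, with 27 of 38 members below 0 (0.95th percentile), but the median was 0.08 after quantile normalization and in the series matrix. About 0.96 of the 24 lists would lie outside these limits by chance if lists were independent. Fibroblast and endothelial markers had 4 measured members, too few to describe as a list.

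Replication-dependent histone genes, whose mRNAs end in a stem-loop in place of a poly(A) tail, had a median of -0.80 (0th percentile), or 0.59 with spike-in scaling against 1.43 for all genes. With percentile scaling 6 of the 17 were at least 2-fold lower. H2AC20, H3C4, H1-4 and H4C8 were 2.76-fold, 2.59-fold, 2.57-fold and 2.49-fold lower. Outside the list, H4C5 was 4.05-fold, H2AC11 3.96-fold and H3C15 3.49-fold lower. Near-identical histone copies can hybridise to the same probe, so the individual genes are uncertain. Most other measured transcripts of classes without a poly(A) tail were lower as well: 133 of 171 small nucleolar and Cajal body RNAs lay below 0 and 38 above, with 37 at least 2-fold lower, and all 6 small nuclear RNAs lay below 0. Of 8 small NF90-associated RNAs 7 lay below 0, and SNAR-C4 lay at 0.81. RNA18SN5 and 5.8S ribosomal RNA (RNA5-8SN5) were 29.7-fold and 15.1-fold lower, but 28S ribosomal RNA (RNA28SN5) lay at -0.33, within the SD between probes of the same gene. Among transcripts with a mean signal at or above the median, as the naming rule asked, the small nucleolar RNA SNORD105B was 3.63-fold lower and the spliceosomal RNA variant RNVU1-18 was 3.34-fold lower. Over the 60 measured replication-dependent histone genes on the array the median was -0.91, against 0.13 for 6 histone variant genes with polyadenylated mRNA, a grouping made after the values were seen. With spike-in scaling the median of the 60 was 0.47 and that of the 6 was 1.52, so the direction against 0 turned while the distance stayed.

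**Figure D3:**
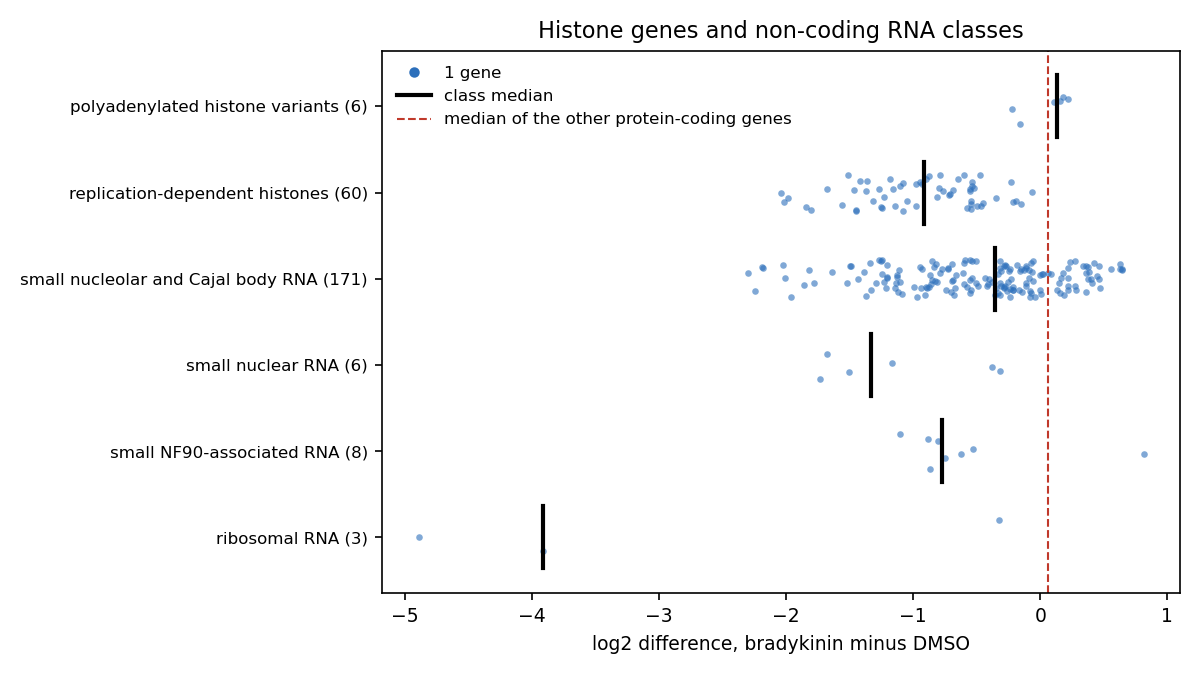
Log2 difference (bradykinin minus DMSO) of each measured gene in 6 classes, with the class median as a black bar and the number of genes in brackets; vertical scatter within a class has no meaning. With percentile scaling the replication-dependent histones lie around -0.91 and the polyadenylated histone variants around 0.13.

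Protein-coding genes other than histones made up 43 of the 78 transcripts at least 2-fold higher and 179 of the 402 at least 2-fold lower. Among the lower ones named by rule were HAPLN2 (3.75-fold), TAF3, a subunit of the general transcription factor TFIID (3.51-fold), MYO5A, an unconventional myosin (3.39-fold), and ALG11, a mannosyltransferase of N-glycan assembly (3.35-fold). LUZP6, which had no gene type in the gene table, was 3.32-fold lower. Each rested on 1 probe. Of the 179, 132 had 1 measured probe, and of the 47 with more, 9 had every probe at least 2-fold lower. In 335 genes a probe was at least 2-fold lower while another was not, and in 89.0% of them the low probe lay nearer the 5′ end of the gene. Among the higher genes outside the lists were the transcription factor genes FOXB1 (3.20-fold), NKX1-2 (2.52-fold) and LHX3 (2.40-fold), TMEM151B (2.82-fold), C20orf204 (4.71-fold) and the long non-coding RNA TUSC8 (3.46-fold). FOXB1, NKX1-2, LHX3 and TMEM151B each rested on 1 measured probe of high GC content (76.7%, 70.0%, 65.0% and 70.0%). The GC trend was estimated only at GC values with at least 50 probes, so it may not reach these probes. Whether GC content raised their values was not settled. For TMEM151B, LHX3 and TUSC8 the gene's other probes were not well above background on either array, and with no background filter these genes lay at -0.077, -0.19 and 0.01.

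A further 2003 genes or transcripts were well above background on the bradykinin array only and 155 on the DMSO array only. Their at-least folds set the brighter array's value against the higher of the dimmer array's lowest signal well above background and the probe's own signal there. These bounds reached 2-fold for 45 and 144 of them. The bradykinin array was brighter, with a 75th percentile of 679 against 312. Its lowest scaled log2 signal well above background was -5.13, against -4.29 on the DMSO array. More dim transcripts could therefore pass on the bradykinin array, and the numbers 2003 and 155 do not by themselves show transcripts switched on or off. The bounds use the same limits: the higher DMSO limit lowers those of the 2003, and the lower bradykinin limit raises those of the 155. The 45 against 144 therefore does not show an excess of lower transcripts. After EGR1 and FOSB the largest higher bound belonged to the unnamed transcript XLOC_007062 (at least 6.49-fold). The largest lower bounds were at least 11.8-fold for the unnamed transcript XLOC_l2_009449, at least 10.6-fold for the sulfotransferase gene GAL3ST4 and at least 9.43-fold for the unnamed transcript XLOC_000223.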

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

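The tests on RNA classes and on immediate early genes, the tests of a lower level of the whole gene, and the comparison with probes at least 2-fold higher, were chosen only after the result was seen.

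The negative-control spots, which no comparison used, had a mean net signal of 44.6 on the bradykinin array against 28.2 on the DMSO array, and Feature Extraction's own quality report put the former outside its range. After background subtraction these spots averaged -4.52 and -3.96.

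RNAs without a poly(A) tail were lower than the bulk of transcripts on the bradykinin array, over several classes: the medians were -0.91 for replication-dependent histones, -1.33 for 6 small nuclear RNAs and -0.36 for 171 small nucleolar and Cajal body RNAs. Fewer cells in S phase would lower DNA replication genes too, but the median of 15 such genes was -0.030 from that of all genes, and would leave small nuclear and nucleolar RNAs in place, which lay at -0.43. A trend with probe GC content or brightness also failed to account for it, since the set stayed at -0.63 or lower from all genes after either was subtracted. Polyadenylated histone variants lay 1.05 above the replication-dependent histones, which is consistent with less copying or labelling of RNA without a poly(A) tail in the bradykinin sample, through different priming, RNA quality or amplification. The set also held 3 ribosomal RNAs, made from a shared precursor, at -4.89 (RNA18SN5), -3.92 (RNA5-8SN5) and -0.33 (RNA28SN5). A real fall shared by these ribosomal RNAs would not part them in this way, so the values argue against it. Nor would an equal loss of copying in every RNA without a poly(A) tail part them, so neither account by itself gives this split. For the other classes a real fall by another route, from treatment or dish, remains open.

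Single probes of protein-coding genes were often at least 2-fold lower where the gene's other probes were not, in 335 genes. A lower level of the whole gene's RNA would lower every probe, but over all 283 genes picked only for a most 5′ probe at least 2-fold lower, the most 3′ probe had a median of -0.078 (bootstrap 95% interval -0.12 to -0.032), and in 9 it was itself at least 2-fold lower. For the 36 genes picked only for a most 3′ probe at least 2-fold lower it stays open, since the most 5′ probe had a median of -0.53 (-0.87 to -0.15) and was at least 2-fold lower in 9. In the 335 genes the low probe lay nearer the 5′ end in 89.0% (Wilson 95% interval 85.1 to 91.9), consistent with RNA far from the 3′ end being copied less in the bradykinin sample, whereas in 18 genes with a probe at least 2-fold higher and another not, the high probe did so in 55.6% (33.7 to 75.4). Use of other transcript ends in treated cells was not tested, and MKI67 (-1.93, -1.91 and -0.29) is an example of such a gene.

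Immediate early genes were higher on the bradykinin array. Subtracting a GC or brightness trend left the list at the 100th percentile, with a median of 0.68 or 0.64 in place of 0.70. Heat shock genes, which stress by heat or misfolded protein would raise, lay at the 41.7th percentile. Both tests argue against those explanations. Receptor activation needs a receptor, and 2 of 2 receptor genes were measured, but this does not show that bradykinin acted through them. Because the 2 arrays lay on 2 slides, 1 group on each, a difference of dish, medium change, slide or scan and the treatment cannot be told apart.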

How the results depend on the processing

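The alternatives on probe GC content, spike-in scaling, RNA class, probe number, the probe nearest the 3′ end and list overlap were chosen after seeing the data. No paired analysis was possible because each group had 1 array and no difference came from a test, and leaving out an array was not possible for the same reason.

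Immediate early and inflammatory genes stayed at the 100th percentile and histones at the 0th under every alternative run, and MAP kinase feedback inhibitors between the 99.6th and the 100th. Of 366 list comparisons 339 kept their call, of 917 for named genes 878 moved by less than the SD between probes of the same gene, and of 32 counts 17 stayed within 1.5-fold. Part of these comparisons could not move. For a gene with 1 measured probe, the brightest and the 3′-most probe give the main value, and some background filters do too. Median scaling shifts every gene alike, so no list percentile could move under it. The 878 and the 339 are therefore not all separate checks.

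Against 78 higher and 402 lower, the counts were 47 and 244 with normexp, 713 and 2488 with no background filter, 34 and 109 in the brighter part by construction, 489 and 1259 at 1.5-fold, 5 and 56 for genes with 2 or more probes on the same side, 14803 and 14 with spike-in scaling, and 43 and 179 for protein-coding genes without histones. With probes well above background on at least 1 array, 592 were higher and 544 lower. The 78 shared 42 genes with the 47 of normexp and 76 with the 85 from the probe nearest the 3′ end. The 402 shared 243 with the 244 of normexp and 367 with the 396 from the probe nearest the 3′ end, a choice that alters nothing for the 12936 genes or transcripts with 1 measured probe. Normexp moved the median of all genes from 0.05 to -0.07.

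Ribosomal proteins moved to the 89.6th percentile with quantile normalization, also 89.6 with the series matrix, 39.1 with the intensity trend subtracted, 9.11 in the brighter part and 5.29 for the mean. Leucocyte markers went to 33.1 with no background filter, 92.3 with at least 1 array, 97.5 with normexp and 96.8 without TYROBP. Interferon genes went to 86.3 (normexp), 97.8 (slide position), 93.7 (no filter) and 93.3 (mean). Some lists came to stand apart: calcineurin and CREB targets at 100 with at least 1 array and 99.4 with no filter; TGF-beta and stress response lists at 99.3 and 98.9 for the mean; mitochondrial genes at 98.2 (slide position), 98.6 (brightest probe) and 98.4 (mean); alveolar markers at 98.2 (series matrix), 98.5 (GC), 99.9 (brightest probe), 98.6 (unmatched) and 98.3 (mean); epithelial and mesenchymal genes at 0.89 (GC) and 1.75 (at least 1 array). The calcineurin and CREB, TGF-beta and stress response lists share members with the immediate early list, so they are not separate from its result. Of 79 named genes 13 turned in sign. Those at least 2-fold higher in the main setting were TMEM151B and LHX3 (-0.077 and -0.19 with no background filter, where probes near background entered the mean). The other 11 lay closer to 0: with normexp SPRY4 (-0.029), DPP4 (-0.11), ALOX5AP (-0.0048), HBEGF (-0.019), ATOH8 (-0.096), HSPA1L (-0.050), OASL (-0.28), AGER (-0.0077) and ITGAM (-0.27); with no background filter NR4A3 (-0.10), AGER (-0.54) and MX2 (0.48). The 9 that turned with normexp had DMSO signals from 18.3 (ITGAM) to 48.1 (SPRY4), under the normexp offset of 50, which weighs most on dim probes. The cause of the turns among these 11 was not tested.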

Other observations

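The tests and gene choices in this part were made after the values were seen.

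IL6 was at 2.06 (0.86 with normexp). Other single genes higher on the bradykinin array were CLCF1, an IL-6 family cytokine, by 1.81-fold (processed signal 633 to 2490 against scaling of 2.18), SOCS3 by 1.81-fold, RASD1 by 2.23-fold and GEM by 2.21-fold. With normexp RASD1 and GEM lay at log2 differences of 0.80 and 0.66, under the 2-fold limit. LIF had probes at -0.51 and 0.59 and a mean of 0.04. No list or count tested these genes as a group.

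Not every classical early gene took part. MYC was 1.14-fold higher (-0.033 with no background filter), whereas IER2, KLF10 and SGK1 had log2 differences of 1.18, 1.03 and 1.02. SLC25A25, a calcium-regulated mitochondrial carrier gene, was 1.68-fold higher. Of common reference genes, GAPDH lay at 0.03 and ACTB at -0.37 over 2 probes, so ratios to ACTB and to GAPDH would differ by about the SD between probes; GAPDH lay at -0.05 after a GC trend was subtracted and at 0.25 in the series matrix.

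28S ribosomal RNA (RNA28SN5) parted from the other ribosomal RNAs, at -0.33 over 4 probes from -0.55 to 0.07, against -4.89 for RNA18SN5 and -3.92 for RNA5-8SN5, although the cell makes all 3 from 1 precursor. Within histone genes the probes also disagreed: H2AC6 gave -1.64, -1.13 and 0.08, and H2BC12 gave -0.67 and 0.24.

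Over 3380 protein-coding genes with measured probes at least 100 bases apart, the difference at the most 5′ probe minus that at the most 3′ probe had a median of -0.10, and the 5′ probe was lower in 59.7%. Where the probes lay farther apart than the median of 5636 genomic bases the median was -0.19, and where they lay closer it was -0.03.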
